A study of Homo sapiens with 6 samples.

How the data were processed

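RNA bound to chromatin was measured in A549 cells, a human lung adenocarcinoma line, in 6 libraries that fall into 2 groups of 3. Per the labels' protocols, the cells carried a stable knockdown of METTL3, the catalytic subunit of the nuclear enzyme that writes N6-methyladenosine (m6A) on RNA, and were rescued from a lentiviral vector with wild-type METTL3 (METTL3-WT) or with a form the labels name 3KR (METTL3-3KR), switched on for 48 h with 2 ug/ml doxycycline. The changed residues of 3KR are not given in the sources used here. Cytoplasm and soluble nucleoplasm were removed by lysis, a sucrose cushion and urea, and RNA of the remaining chromatin pellet was made into strand-specific total RNA libraries and sequenced as read pairs. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

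The deposited table holds raw counts, not normalized, per region and strand, with 1 column per library, so replicates were not pooled. Per the submitters' processing notes, Trim Galore 0.6.7, STAR 2.7.1a, HTSeq 2.0.5 and DESeq2 1.42.1 were used with the build hg38. Their roles, how the regions were chosen, and the settings for strand and for reads with several matches are not given in the sources used here. The table has 130223 rows: 94108 named eRNA, which are both strands of 47054 enhancer regions with a median length of 1124 bases and up to 76941 bases, and 36115 named paRNA, which are promoter regions. Of the promoter regions, 35722 span 1100 bases from 1000 upstream to 100 downstream of a transcription start. All rows name a region, and 41960 had no count in any library.

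The strand in a promoter row's name is that of the gene, while its counts are of the opposite strand. Among 3129 promoter regions with at least 10 counts that lie inside an enhancer region, 44.2% had more counts than the enhancer row of the strand in the name, which shared reads on that strand would not allow, and 1.15% had more than the enhancer row of the opposite strand. Enhancer and promoter rows therefore share reads where they overlap: 12862 enhancer rows share bases with a promoter row of the same RNA strand. The RNA component of RNase MRP, RMRP, is counted in both an enhancer and a promoter row in this way.

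Regions were placed on genes with the RefSeq genes of GRCh38.p14, the same assembly as hg38, given as starts and ends without strand, exons or sequence. A gene's strand was taken from promoter rows that start within 1000 bases of either of its ends (24311 genes), or else from its reads, where 1 strand held at least 20 times the counts of the other and at least 100 counts in regions that overlap it by at least 30% of the bases of either (2019 genes). This gave a strand to 26330 of 59792 genes and to 17364 of 20056 protein-coding genes. Among 5012 protein-coding genes with both kinds of evidence, 97.0% had the same strand by both. Each row was then called sense or antisense to an annotated gene, intergenic, or of unknown strand. A row belongs to the gene whose start is nearest within 10 kb, so some rows of a gene list lie in or beyond a neighbouring gene, and the text says so where such a row is named. Exons, introns and UTRs cannot be told apart here.

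Counts per library in the table ran from 5774974 to 7702281. The table covers part of each library, and the depth beyond it was not used. The 10 rows with the most counts held 17.2% to 22.0% of the total. Pairs of libraries of the same group differed by 1.69 to 5.77 times sampling noise (chi-square per degree of freedom) and pairs across groups by 10.5 to 17.0, so no library was a copy of another and n is 3 per group.

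Differences between METTL3-3KR and METTL3-WT were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, the default filter on low counts (34306 rows kept), the robust quasi-likelihood test and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 called changed. Log2 fold changes are METTL3-3KR relative to METTL3-WT, and their standard error (SE) is the log2 fold change divided by the root of the F statistic. CPM values, counts scaled to a common library size, were computed from the deposited counts with TMM library sizes. The text calls a row higher or lower where it passed this test. Gene lists and row classes were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01, beside an estimated correlation and fry. Lists with fewer than 5 tested rows were not tested. The list of mitochondrial genes matched no row, because the gene table names the chromosome and its genes otherwise than the counts and the list do, so these rows were not placed on genes and are given apart. Shares of counts were compared with a two-sided exact permutation test, which cannot go below p = 0.1 with 3 against 3. Relations across genes used 100000 permutations, and intervals are 95% bootstrap intervals of 2000 draws, computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with plots from matplotlib 3.10.9.

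Named rows were chosen by a rule fixed before the data were examined: every tested row of METTL3; the 12 higher and 12 lower rows with the largest change, and the 4 of each direction with the smallest p, among changed rows with a mean CPM of at least 7.38 (the median of tested rows) and groups that do not overlap; the 4 of each direction per class by size; and up to 4 changed rows per gene list with the smallest p, or the 1 with the smallest p where none changed. This gave 114 rows. Rows named outside it were chosen after their values were seen and are named as such. The 24 gene lists were fixed before the data were examined too.

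The replicate numbers in the labels are shared by both groups. The deviations of same-numbered libraries from their group means correlated at 0.22, 0.17 and 0.57 over rows with a mean of at least 50 counts. A fit that takes the numbers to pair the samples, with the replicate number as a block, was therefore run beside the main one. The main fit, which gave the reported calls, does not use the pairing. Replicate 1 of METTL3-WT correlated more closely with replicate 2 of METTL3-3KR, at 0.36. The first principal component, with 61.3% of the variance, separated the groups, and the second, with 16.3%, set replicate 3 of both groups apart. Other alternatives were DESeq2 size factors, library size only, the DESeq2 1.42.0 Wald test, no filter and a mean of at least 50 counts, a 2-fold threshold, each RNA class fitted alone, each library left out in turn, other set tests, and lists by overlap with the gene body.

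The main test was run on simulated counts for the same 34306 rows with 200 rows changed and a set of 60 rows shifted together. It recovered 23.9% of rows changed 1.5-fold, 61.2% of those changed 2-fold and 98.5% of those changed 4-fold. It also called 20 of 34046 unchanged rows. Even with all 200 changed and 60 shifted rows called, these 20 exceed the share of false calls that the adjusted p threshold allows. Camera found the shifted set, whose rows were drawn independently, so lists with correlated rows were not tried. Most changes of 1.5-fold were thus missed in the simulation, which was not split by count. Far fewer rows changed there than the 8770 called in the data, which makes the adjusted p stricter, so recovery in the data may differ. PCR copies carry no molecular identifier, so errors from counting alone are not given.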

Results

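Chromatin-associated RNA was sequenced from A549 lung adenocarcinoma cells with METTL3 knocked down and rescued by METTL3-WT or METTL3-3KR, with 3 libraries per group. Library totals in the count table were 6486791, 6421808 and 7702281 for METTL3-WT replicates 1 to 3, and 5774974, 6339140 and 7440485 for METTL3-3KR. The series title concerns m6A on RNAs from enhancers and promoters and acetylation of METTL3 and of histone H3 at lysine 27, so the comparison asks how the form of METTL3 changes these RNAs on chromatin. Of the enhancer counts, 93.2% (METTL3-WT) and 93.4% (METTL3-3KR) lay on the sense strand of an annotated gene, so most values below include the gene's own transcript. Of the promoter counts, 84.0% (METTL3-WT) and 83.7% (METTL3-3KR) lay on the sense strand of a gene. All positions are on hg38, and CPM values are means ± SD with n = 3 per group.

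METTL3 transcripts were present on chromatin in both rescues, slightly higher with METTL3-3KR. A small amount of RNA from the opposite strand at the METTL3 start was higher with METTL3-3KR. The METTL3 row on chromosome 14 from 21509946 to 21511401, sense strand, held 816, 796 and 916 counts with METTL3-WT and 840, 972 and 898 with METTL3-3KR. That is 120 ± 4.22 against 148 ± 19.5 CPM, a log2 fold change of 0.30 (SE 0.11, edgeR adjusted p = 0.0395) that missed the threshold in 9 of 13 alternatives, where the adjusted p ran from 0.00266 to 0.198. The antisense METTL3 row held 6, 9 and 4 counts against 23, 24 and 21, a log2 fold change of 2.01 (SE 0.36, adjusted p = 2.71e-04). Both groups carry a rescue construct and reads of its cDNA cannot be told from those of the gene, so METTL3 does not check which form a library carries.

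The form of METTL3 went with a broad difference in chromatin RNA. Form and rescued cells coincide in these libraries, so the form cannot be told apart from any other difference between the rescued cells. RNA from many enhancer regions was higher with METTL3-3KR, and the largest rises were in RNA that was scarce with METTL3-WT, such as the strand opposite VMP1. The largest falls were upstream of FMNL1. Of 34306 rows tested with edgeR, 8770 changed (25.6%), 4934 higher and 3836 lower. The number lower was 2519 without METTL3-WT replicate 2 and 2331 with the DESeq2 Wald test. The median size of the log2 change among them was 0.81, against a median SE of 0.21 over all tested rows. The groups did not overlap in 13630 rows (39.7%), where chance gives 10%. With the replicate number as a block, 11733 rows changed, 54.0% of them higher, and all 8770 were among them. With library size only, which lowered the median of all rows from -0.01 to -0.13, 39.8% of 9519 changed rows were higher, against 56.3% of those reported, so the balance of higher and lower rows rests on the scaling.

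The highest rise among named rows was antisense to VMP1, an autophagy gene whose end overlaps the microRNA-21 precursor, on chromosome 17 from 59789813 to 59819039. Its CPM went from 2.95 ± 0.468 to 255 ± 20.4, a log2 fold change of 6.43 (SE 0.15, adjusted p = 1.41e-17). The sense strand of the same region, chosen after its value was seen, rose by 1.77. A row near LOC105374414 on chromosome 2 rose by 5.60, a row of USP2, which encodes a deubiquitinase, by 5.11, and a row antisense to APOL1 by 4.47. MROH2A on chromosome 2 rose by 4.07, from 2.55 ± 0.118 to 43.1 ± 5.58 CPM, while HJURP, which loads the centromeric histone CENP-A, fell by 1.72 on the opposite strand of the same region, a row chosen after its value was seen. A row of UGT1A10, a glucuronosyltransferase gene, rose from 38.8 ± 0.612 to 267 ± 7.71 CPM (log2 fold change 2.78, SE 0.10, adjusted p = 4.3e-14). MROH2A starts at 233775724, past the end of UGT1A10 at 233773300 on the same strand. Whether MROH2A rose apart from UGT1A10 was not tested. Rows of LMCD1, a LIM domain gene, rose by 3.77, 3.91 and 4.01.

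Intergenic rows past the end of SLC7A5, which encodes a leucine transporter subunit, rose while the gene did not. The row on chromosome 16 from 87803281 to 87810547 went from 18.8 ± 1.01 to 249 ± 2.83 CPM (log2 fold change 3.73, SE 0.11, adjusted p = 1.02e-15), and its named neighbours rose by 3.70 and 3.86. The row over SLC7A5 itself, looked up after these values were seen, had a log2 fold change of -0.01 (SE 0.13, adjusted p = 0.976). A row near HAP1, which rose by 4.35, lies 13.8 kb past the end of JUP on its strand.

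Lower rows clustered upstream of FMNL1, a formin gene, on the plus strand of chromosome 17. The row from 45196264 to 45199232 fell from 42.6 ± 5.58 to 1.82 ± 0.798 CPM (log2 fold change -4.56, SE 0.22, adjusted p = 2.9e-12), and the other named rows there had log2 fold changes of -3.77, -4.17 and -4.05. The row at -3.77 also lies 12.1 kb past the end of HEXIM2 on its strand. The sense rows of HEXIM2 had a mean log2 fold change, weighted by CPM, of -0.40. The row that spans the FMNL1 start, chosen after its values were seen, as were the next, was at -2.43, and enhancer rows further inside FMNL1 fell less, at -1.06, -1.06 and -1.02. Other named falls were LOC124904284 (-4.01), SH3BP5 (-2.75, -3.38 and -2.85), LAMA4 (-2.80), ANKRD30A (-2.69) with an intergenic row near it on chromosome 10 (-2.74), and PKDCC (-2.29). A row named for LOC105375520 (-3.16) lies 0.735 kb past the end of AKR1B10.

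**Figure D1:**
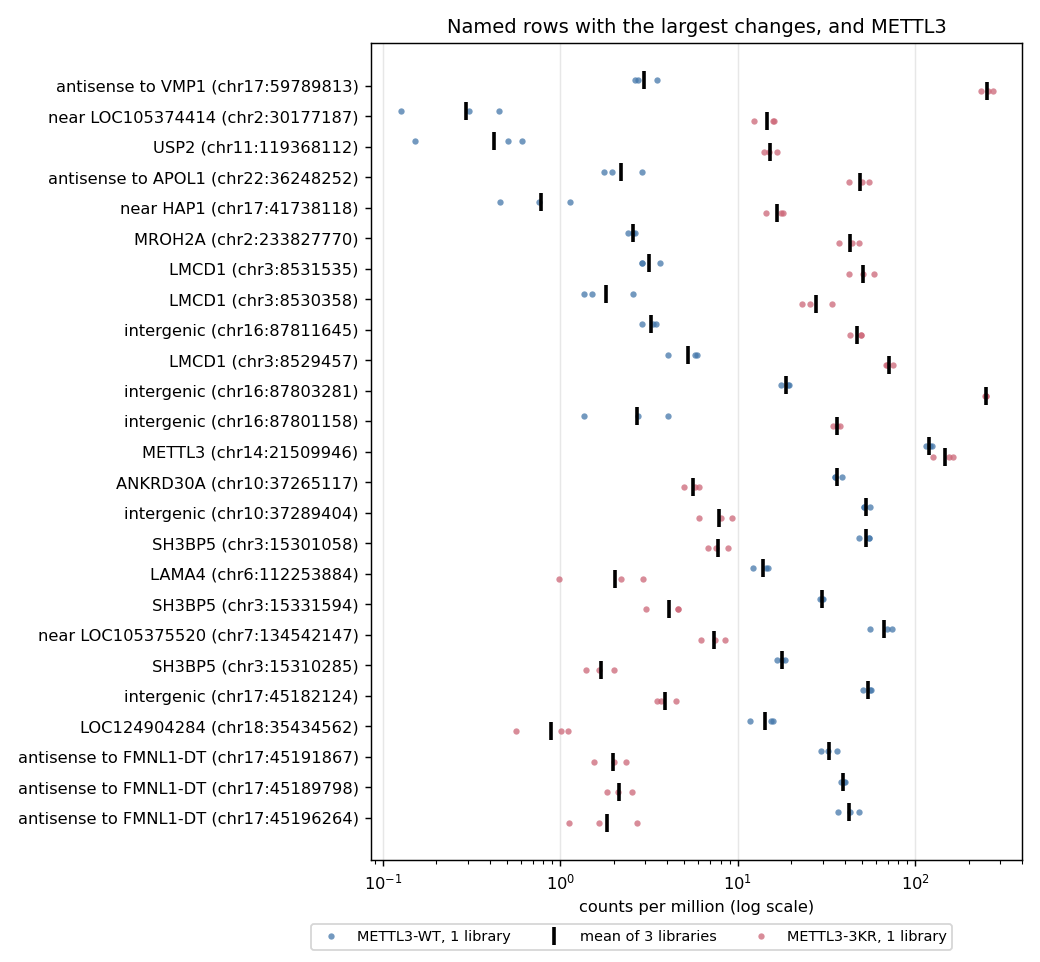
CPM on a log axis in each library (blue METTL3-WT, red METTL3-3KR, black tick the group mean, n = 3) for the 24 named rows with the largest changes and METTL3. The 24 were chosen among changed rows whose groups do not overlap, so their separation follows from the choice, and METTL3 differs by a log2 fold change of 0.30.

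**Figure D2:**
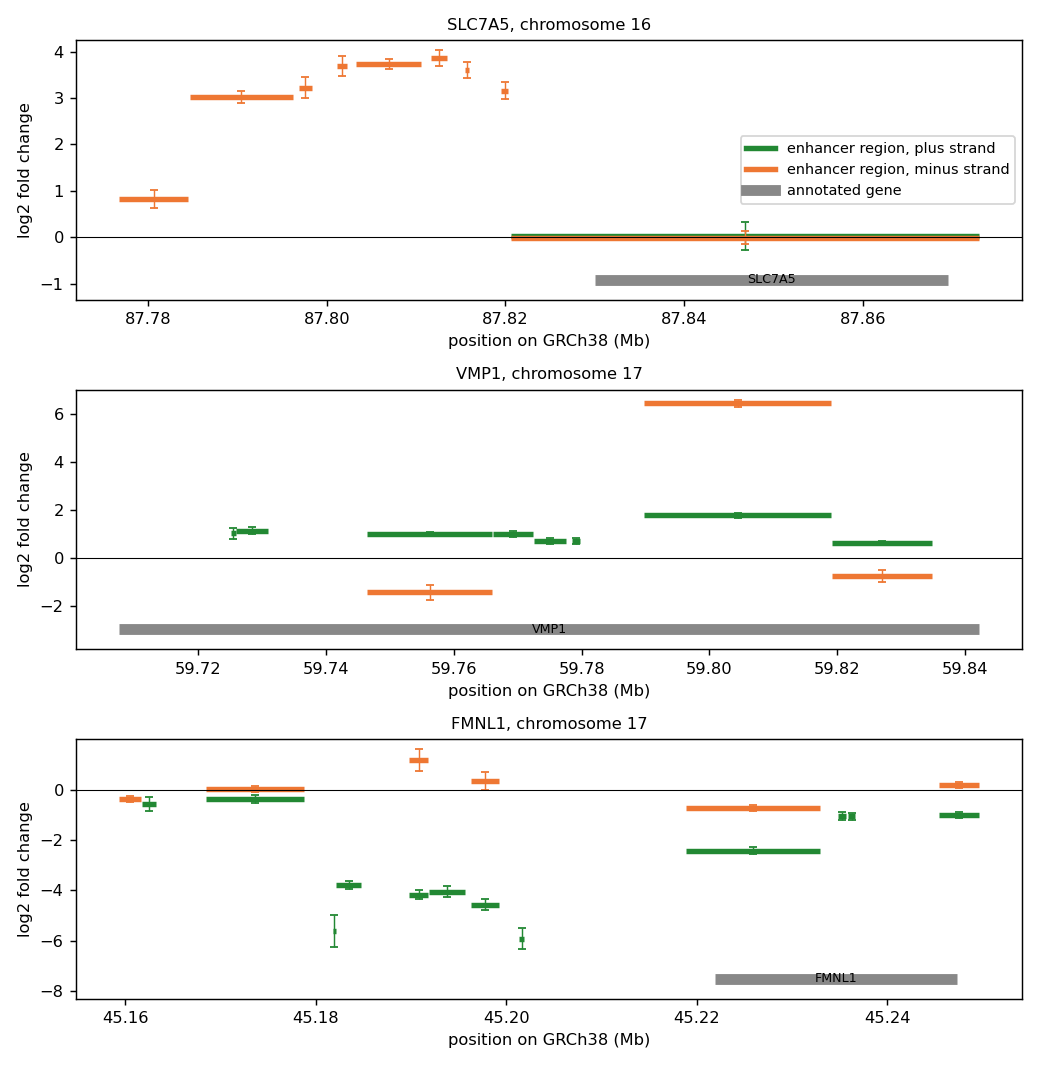
Log2 fold change of each row ± SE by position around SLC7A5 on chromosome 16, and VMP1 and FMNL1 on chromosome 17, with the plus strand in green, the minus strand in orange and genes in grey. Rows past SLC7A5 rise by up to 3.86 while the gene stays at -0.01, and the minus strand of VMP1 rises by 6.43 in a single region.

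With the scaling used, enhancer RNA was higher more often than lower with METTL3-3KR. Promoter rows, which count the strand opposite to their gene, had no clear balance. Most of them lay on the sense strand of another gene. Intergenic enhancer RNA had the highest median and was the only class past camera with the preset correlation. With the estimated correlation it stood no better than antisense enhancer RNA (camera adjusted p = 0.0918 and 0.0911). These classes address the enhancer and promoter RNAs of the series title. Among enhancer rows, 4238 were higher and 2996 lower (58.6% higher), and with library size only 42.8% were higher. Among promoter rows, 696 were higher and 840 lower (45.3% higher), against 27.4% with library size only, and 57.1% with 693 higher and 521 lower when promoter rows were fitted alone. With the replicate number as a block, 955 promoter rows were higher and 1274 lower (42.8% higher). The median log2 fold change was 0.01 for enhancer rows and -0.07 for promoter rows, and the shift between them missed the threshold (camera adjusted p = 0.0734), but passed it with the estimated correlation, at 0.0072 for enhancer and 0.0422 for promoter rows.

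Intergenic enhancer rows had a median log2 fold change of 0.18, with 422 of 1838 higher and 181 lower (camera adjusted p = 0.0285). That shift missed the threshold with the estimated correlation (0.0918), without METTL3-WT replicate 3 (0.0694) and without METTL3-3KR replicate 2 (0.0721). Antisense enhancer rows had a median of 0.09, with 285 of 1331 higher and 145 lower (adjusted p = 0.131). With library size only, the intergenic median was 0.07 and the antisense median -0.02. Relative to the median of all rows, the intergenic median was 0.20 both ways and 0.08 with no filter on low counts, and the antisense median 0.10 both ways, 0.05 with a mean of at least 50 counts and 0.18 without rows that share bases with promoter rows, an alternative chosen after the data were seen. Sense enhancer rows had a median of -0.00 and a mean of 0.03, with 3303 of 21052 higher and 2447 lower (adjusted p = 0.547). Promoter rows on the sense strand of another gene had a median of -0.08 with 480 higher and 658 lower (adjusted p = 0.109), and those off the sense strand of genes 0.04 with 137 higher and 69 lower (adjusted p = 0.537).

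The row holding MALAT1, a nuclear long noncoding RNA, took 9.22 ± 0.606% of counts with METTL3-WT and 12.5 ± 1.33% with METTL3-3KR, and its libraries did not overlap (exact permutation p = 0.1, the smallest that 3 against 3 allows). Promoter rows took 13.7 ± 0.564% and 12.7 ± 0.618% (exact permutation p = 0.2), and the row of NEAT1, the RNA scaffold of paraspeckles, 1.78 ± 0.0219% and 1.91 ± 0.144% (exact permutation p = 0.2). RMRP took 3.87 ± 0.689% and 3.59 ± 0.392% (exact permutation p = 0.7). This test does not use the pairing of the replicate numbers: the promoter share was lower and the NEAT1 share higher with METTL3-3KR in all 3 numbered pairs. Of 9 shares tested this way, none had an adjusted p under 0.36. In the edgeR test, looked up after the shares were seen, both were higher on chromosome 11: the MALAT1 row had a log2 fold change of 0.55 (SE 0.08, adjusted p = 8.87e-05) and the NEAT1 row of 0.22 (SE 0.06, adjusted p = 0.0135). RMRP was not changed there (adjusted p = 0.988).

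Among changed promoter rows with a mean CPM of at least 7.38 and groups that do not overlap, the largest rises were DPH1 (log2 fold change 3.20), an enzyme gene of diphthamide synthesis, MAFF (2.58), a small MAF transcription factor, IGFBP7 (2.25) and FOXN3 (2.17). The largest falls among them were an intergenic row on chromosome 17 from 19736682 to 19737782 (-2.52), EPHA6 (-2.23), a row antisense to SH3BP5-AS1 (-2.09) and DDIT4 (-2.03), a stress-induced inhibitor of mTORC1. Rows are named here by the gene they overlap, which need not be the gene whose promoter they cover. The IGFBP7 and EPHA6 rows are on the sense strand of those genes but belong to the starts of IGFBP7-AS1 and LOC124909397. The strand of DPH1, MAFF, FOXN3 and DDIT4 could not be derived, so whether their rows are sense or antisense is not known. Those rows were placed on no gene's start, so whose promoters they are is not known either.

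Promoter and enhancer rows placed on the same gene moved together. Some of these regions overlap and share reads. Rows go to the nearest start, and 6354 of 8263 tested promoter rows lay on the sense strand of another gene. Both kinds of row can thus hold 1 neighbouring transcript, which leaving out overlapping regions does not remove. The relation was weaker without the overlapping regions, but not in the few genes with RNA off the sense strand of annotated genes. Across 2565 genes, the mean log2 fold changes of promoter and enhancer rows had a Spearman correlation of 0.65 and a Pearson correlation of 0.67 (two-sided permutation p = 1e-05 and adjusted p = 1e-05 for each, the smallest the permutations can give), and 77.0% had the same sign. Without enhancer rows that overlap promoter rows, 1381 genes gave 0.47 for both. Among those, rows off the sense strand of annotated genes gave a Spearman correlation of 0.72 and a Pearson correlation of 0.75 in 137 genes. These 3 relations are across genes, which are not independent replicates, and the last pair of sets was chosen after the data were seen.

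RNA of replication-dependent histones and of cell cycle genes was lower on chromatin with METTL3-3KR. RNA of NRF2 targets, which protect against oxidants, and of cholesterol and lipid synthesis genes was lower too, while that of targets of YAP and TEAD, which drive growth and adhesion genes, was higher. These lists ask which programmes differ between the rescues. Of 24 lists, 22 had enough rows, and 6 passed camera with the preset correlation. None of the 6 passed with an estimated correlation, where the smallest adjusted p was 0.113.

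Replication-dependent histones had 54 rows with a median log2 fold change of -0.99 (camera adjusted p = 2.4e-17), 2 higher and 41 lower over all rows, and the same counts adjusted over the list alone. H1-3 fell by 1.66, H2AC4 by 1.24, and rows nearest the H4C9 start, which overlap H2BC12, by 1.18 and 1.21. Histone genes have near-identical copies that share reads, so single copies are uncertain. The cell cycle list had a median of -0.64 (adjusted p = 3.55e-10), with 2 rows higher and 31 lower, or 2 and 33 adjusted over the list alone. CDC20, an activator of the anaphase-promoting complex, fell by 0.77 and UBE2C, its ubiquitin-conjugating enzyme, by 1.05, while a row antisense to CCNB2 rose by 1.60. The row nearest the MCM5 start, at -1.70, lies 0.965 kb past the end of HMOX1 on its strand.

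NRF2 targets had a median of -0.36 (camera adjusted p = 8.07e-06), with 7 rows higher and 31 lower, or 7 and 32 adjusted over the list alone. AKR1B10, an aldo-keto reductase gene, went from 3158 ± 76.9 to 1615 ± 93.5 CPM (log2 fold change -0.97, SE 0.07, adjusted p = 2.05e-09). TKT, a pentose phosphate enzyme gene, had a log2 fold change of -1.07, UGDH of -0.77 and ALDH3A1, an aldehyde dehydrogenase gene, of -1.66. The cholesterol and lipid list had a median of -0.18 (adjusted p = 0.0251), with 3 higher and 11 lower in both counts, the second adjusted over the list alone. SCD, the stearoyl-CoA desaturase gene, had a log2 fold change of -2.09, ACLY of -1.48, FDFT1 of -0.95 and SREBF1, the regulator of lipid synthesis, of -0.77.

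YAP and TEAD targets had a median of 0.29 (camera adjusted p = 0.00447), with 11 rows higher and 2 lower in both counts, the second adjusted over the list alone. WWC1 rose by 0.60, AJUBA by 0.56 and AMOTL2 by 0.44, and the row nearest the CCN1 start, which lies in DDAH1, by 1.25. By gene body the list's median of 0.19 lay at the 93.8th percentile of random lists of the same gene length and expression. Ribosomal protein genes had a median of -0.18 (adjusted p = 0.0472), with 6 rows higher and 14 lower, or 6 and 16 adjusted over the list alone. The ribosomal protein genes' call was lost without METTL3-WT replicate 1 (0.195), without METTL3-3KR replicate 3 (0.280), without both libraries numbered 3 (0.104) and with fry (0.282). RPS4X fell by 0.58, while a row near RPS3 rose from 1.94 ± 0.302 to 5.21 ± 1.60 CPM, a row antisense to RPS6 by 1.76 and PLEKHG2, nearest the RPS16 start, by 0.96.

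The m6A writers, erasers and readers (median -0.22, camera adjusted p = 0.27) had 3 rows higher and 5 lower, or 4 and 9 adjusted over the list alone. IGF2BP1, an m6A reader, had a log2 fold change of -1.14, LOC124904020 on its opposite strand -1.75, and HNRNPC 0.31. Histone acetylation genes (median -0.23, adjusted p = 0.123) had 2 higher and 4 lower, or 2 and 3 adjusted over the list alone: HDAC7 was at -0.65, HDAC5 at 0.87, SIRT1 at 0.63, and RELL2, nearest the HDAC3 start, at -0.56. Nuclear RNA decay genes (median -0.12, adjusted p = 0.323) had 0 higher and 3 lower, or 0 and 1 adjusted over the list alone, with EXOSC2 at -0.77, CPSF3 at -0.47 and ZDHHC16, nearest the EXOSC1 start, at -0.69, calls that were lost in 2, 5 and 7 of 13 alternatives. Elongation genes (median 0.14, adjusted p = 0.594) had 4 higher and 2 lower, or 2 and 0 adjusted over the list alone, with AFF1 at 0.73, a row near PAF1 at 0.98, MAPK6, nearest the LEO1 start, at 1.10 and HEXIM1 at -0.30. The MAPK6 call was lost in 6 of 12 alternatives, and those of HEXIM1, RELL2, HNRNPC and SIRT1 in 6, 4, 3 and 1 of 13.

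Immediate early genes (median -0.01, camera adjusted p = 0.47) had 9 rows higher and 13 lower, or 14 and 14 adjusted over the list alone. FOS, a transcription factor induced within minutes of a stimulus, fell by 1.23, a row past it by 1.89 and JUNB by 0.77, while the row in DDAH1, nearest the CCN1 start, rose by 1.25. Hypoxia and glycolysis genes (median -0.05, adjusted p = 0.27) had 7 higher and 11 lower in both counts, the second adjusted over the list alone; PKM, the pyruvate kinase gene, fell by 1.43 and 0.83 in its larger rows and from 29.6 ± 4.63 to 10.3 ± 2.92 CPM in a small one, and BNIP3L rose by 1.48. Stress response genes (median 0.05, adjusted p = 0.674) had 4 higher and 6 lower, or 5 and 6 adjusted over the list alone, with DDIT3 at 1.01, SNHG1, nearest the SLC3A2 start, at -0.66, and rows antisense to and near SHMT2 at 2.79 and 3.05. Targets of p53 (median 0.03, adjusted p = 0.983) had 7 higher and 5 lower, or 7 and 7 adjusted over the list alone, with MDM2 at 0.47, BTG2 at -0.79 and rows near PHLDA3 at 1.35 and 1.94.

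Interferon response genes (median 0.21, camera adjusted p = 0.329) had 4 rows higher and 3 lower, or 4 and 2 adjusted over the list alone. ISG20 rose by 0.93, ISG15 by 1.01 and AEN, nearest the ISG20 start, by 0.49, with the ISG15 call lost in 3 of 12 alternatives and that of AEN in 1 of 13. The NF-kB list (median 0.12, adjusted p = 0.27) had 13 higher and 6 lower, or 14 and 6 adjusted over the list alone, with NFKB2 at 0.64, a row near TRAF1 at 1.05, and rows near and antisense to CCL2 at 1.64 and 1.78. Mesenchymal transition genes (median -0.07, adjusted p = 0.255) had 6 higher and 13 lower in both counts, the second adjusted over the list alone: TPM1 was at 0.75, KRT18, nearest the KRT8 start, at -0.60 and a row antisense to ITGB1 at -1.29. Chromatin-associated noncoding RNAs (median 0.05, adjusted p = 0.592) had 8 higher and 4 lower, or 8 and 7 adjusted over the list alone, with CCAT1 at 1.24, CYTOR at 0.90, LINC-PINT at 0.60 and a row near MIR31HG at -0.57. The small nuclear RNA list (median -0.23, adjusted p = 0.47) had 0 higher and 1 lower, or 0 and 2 adjusted over the list alone, with a row antisense to RNU1-1 at -0.70, a call lost in 1 of 13 alternatives.

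**Figure D3:**
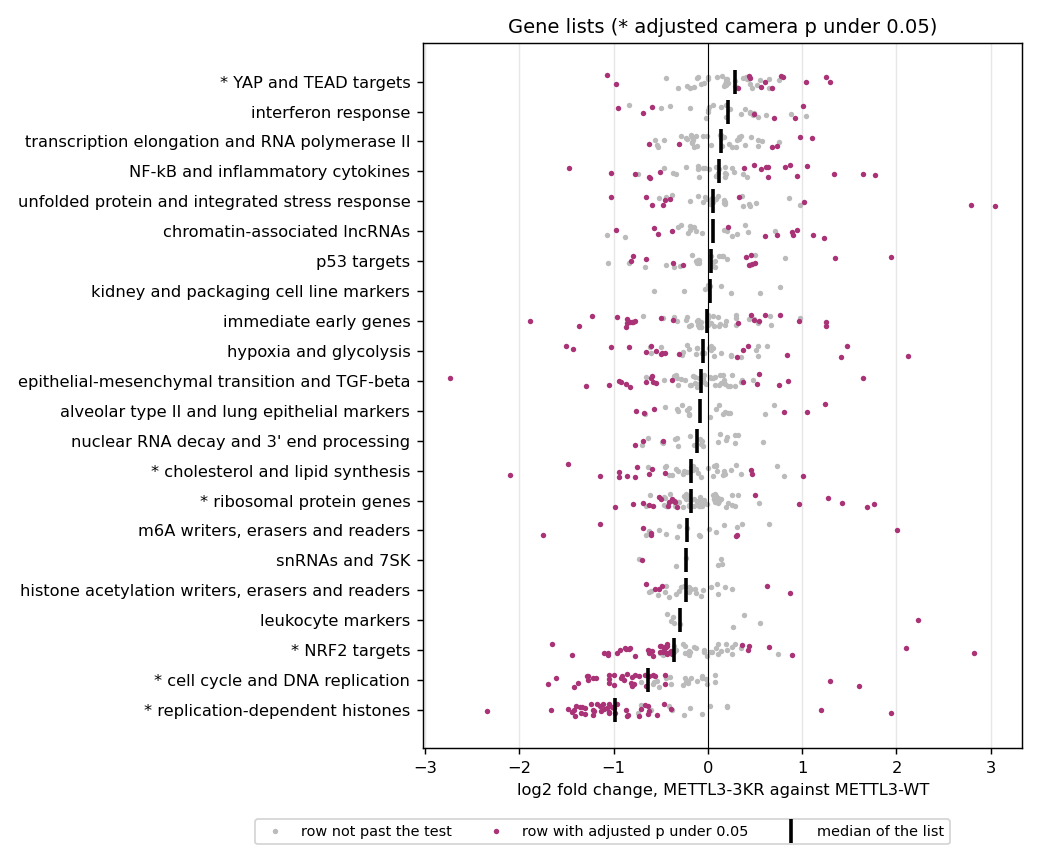
Log2 fold change of each tested row by gene list, with the median as a black tick and an asterisk where the camera adjusted p with the preset correlation is under 0.05. Histones have the lowest median, -0.99, and YAP and TEAD targets the highest of the lists with an asterisk, 0.29.

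Markers of the lung epithelium changed both ways, and few rows of other cell types' markers changed. These lists compare cell type markers between the rescues, and do not check which cells both groups share. Alveolar and lung epithelial markers (median -0.09, mean 0.02, camera adjusted p = 0.607) had 3 rows higher and 3 lower in both counts, the second adjusted over the list alone. ELF3, an epithelial transcription factor, fell by 0.76 and a row of KRT7 by 0.57, while GATA6 rose by 1.05 and TTC6, near the FOXA1 start, by 1.24. Over all tested sense enhancer rows of KRT7, looked up after, the mean log2 fold change weighted by CPM was -0.015. Leukocyte markers had 9 rows, with a median of -0.29, a mean of 0.18, a downward camera test (adjusted p = 0.983) and an upward fry test (adjusted p = 0.0495). The row of this list that changed, antisense to HBA1, rose by 2.23 to 3.16 ± 0.704 CPM; HBA1 is a globin gene of red blood cells that the list also holds, so it says nothing about leukocytes. Kidney and packaging cell line markers (9 rows, median 0.02, adjusted p = 0.94) had 0 changed, with INA at -0.57 (adjusted p = 0.0872). INA passed the threshold with the replicate number as a block (0.0328), with library size only (0.0375) and without METTL3-WT replicate 2 (0.0271). Fibroblast markers had 4 tested rows with 0 changed, among them COL6A1 at 0.45 (adjusted p = 0.158). The mitochondrial gene list could not be tested, because its symbols and the chromosome's name differ between the sources. The 7 tested rows of that chromosome, all promoter rows, had log2 fold changes from -0.40 to 0.88, with 0 changed in edgeR, 0 at an unadjusted p under 0.05 and 0 with the DESeq2 Wald test. They took 0.359 ± 0.0657% of counts with METTL3-WT and 0.290 ± 0.108% with METTL3-3KR (exact permutation p = 0.5).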

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

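The libraries without both numbered 3, the rows off the sense strand of genes and the leaving out of shared reads were alternatives chosen after the data were seen. The rest were planned. The count of changed rows stayed within 1.5 times 8770 with DESeq2 size factors, no filter and each RNA class fitted alone. The same held without shared reads and without both numbered 3. It also held with the DESeq2 Wald test (5865), library size only (9519), the replicate block (11733) and without each library in turn (6348 to 8874).

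A mean of at least 50 counts left 5365 changed rows, 3068 higher and 2297 lower (enhancer 2751 and 1873, promoter 317 and 424), as fewer rows were tested. Only rows off the sense strand of genes, 1404 changed, 761 higher and 643 lower (enhancer 636 and 502, promoter 125 and 141), again from fewer rows. At least 2-fold, 3008 changed, 1896 higher and 1112 lower (enhancer 1595 and 842, promoter 301 and 270), by its construction. The DESeq2 Wald test called 2331 rows lower (enhancer 1877, promoter 454) and 433 promoter rows higher. Promoter rows lower were 1348 with library size only, 1274 with the replicate block and 521 with each class fitted alone; the cause was not tested. Without each library in turn, 2519 to 3922 rows were lower (enhancer 1985 to 3063, promoter 534 to 859), the fewest without METTL3-WT replicate 2.

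The shift of promoter rows against the others passed the threshold with the estimated correlation (0.0422), and that of enhancer rows too (0.0072). Fry, which tests a class against no change and not against other rows, gave 0.0376 for promoter, 0.000119 for enhancer and 0.00122 for antisense rows. Leaving out each library gave 0.0459 to 0.154 for either, under the threshold without METTL3-3KR replicate 1. The intergenic shift missed it with the estimated correlation (0.0918) and ran from 0.0161 to 0.0721 without each library, missing it without METTL3-WT replicate 3 (0.0694) and METTL3-3KR replicate 2 (0.0721). The cause was not tested.

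With the estimated correlation 0 of 22 gene lists passed camera, against 6; fry gave 9, of which 5 were among the 6 and ribosomal protein genes were not, gene body overlap 9 of 23 and the replicate block 6. Leukocyte markers turned from lower to higher with fry (0.0495); the cause was not tested. Of 114 named rows, 101 kept their call in every one of the 13 alternatives that tested them and 0 reversed; a mean of at least 50 counts left 94 of them to test. Calls were lost for METTL3 sense in 9, ZDHHC16 in 7, HEXIM1 in 6, MAPK6 in 6 of 12, CPSF3 in 5, RELL2 in 4, HNRNPC in 3, ISG15 in 3 of 12, EXOSC2 in 2, and AEN, SIRT1 and the row antisense to RNU1-1 in 1 each. INA gained one in 3.

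Simulated changes of 1.5-fold were recovered in 23.9% of the rows given them; recovery was not split by count, so what depth limits was not tested apart.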

Other observations

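The expression level, gene length, change of the gene itself and strandless background were tested as planned before their results were seen; the count of splits, both tests of cytoplasmic mRNA and the test of low counts were chosen after. With METTL3-3KR, RNA of histone and cell cycle genes on chromatin was lower, RNA past the ends of genes such as SLC7A5 was higher, and RNA of long genes rose relative to that of short genes. METTL3 writes m6A on nascent RNA, and m6A has been linked to RNA decay and to termination of transcription. A change of the METTL3 form is thus a hypothesis for each of these patterns. Any other difference between the rescued cells coincides with the form and cannot be told from it.

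The 6 libraries make 10 splits into 3 and 3. The real split gave 8770 changed rows in edgeR and the highest of the others 0, among them the other splits that part all numbered pairs. The splits are too few for a share under 0.05, and 1 gave as many rows, the real one.

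Enhancer rows on the sense strand had lower log2 fold changes in short genes than in long genes. The median log2 fold change went from -0.15 in the shortest of 4 groups of rows (median gene length 10.9 kb) through -0.08 and 0.07 to 0.15 in the longest (249 kb). With library size only, the shortest group was at -0.26 and the longest at 0.03, so the difference, 0.29 both ways, holds, while the size of the rise in long genes rests on the scaling. Across 9862 genes the trend had a Spearman correlation of 0.20 (permutation p = 1e-05, the smallest possible). Expression level was argued against, since the longest group minus the shortest was at least 0.26 in each of 4 groups of mean CPM. Less mature cytoplasmic mRNA in the METTL3-3KR fraction stays open. Ribosomal protein rows, whose mRNAs are abundant in the cytoplasm, had a median of -0.23, at the 3.27th percentile of lists of like length and expression. That is inside the 95% range of those lists, -0.236 to -0.008. The lists have the same gene lengths, so the comparison cannot say whether such mRNA makes the length trend. The METTL3 form stays open too, as untested.

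Cell cycle and replication-dependent histone rows were lower, with a median of -0.74 over 77 rows on the sense strand of their genes. Gene length was argued against, as the 0.1th percentile of 10000 matched lists was -0.25. These rows lay below ribosomal protein rows by a difference of -0.51 (95% interval -0.65 to -0.35, drawn over rows). The share of mature mRNA in either set of rows was not measured. The difference therefore cannot decide whether less cytoplasmic mRNA is the whole cause. A lower share of cells in S phase and mitosis, through the METTL3 form, may explain the lower rows, but cell cycle phase was not measured.

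Intergenic enhancer rows within 50 kb past the end of a gene were higher in 322 of 1005 and lower in 76, while 789 intergenic rows past no such gene had 94 higher and 99 lower. The remaining 44, past a gene with no tested sense row, had 6 higher and 6 lower. A change of the gene's counted RNA was argued against, since the row rose more than its gene by a median of 0.32 (95% interval 0.24 to 0.38, 642 genes). Those counts do not separate nascent from mature RNA, so a change of the gene's transcription was not tested apart. Background without strand was argued against by a median difference of 0.32 between the gene's strand and the opposite strand (0.17 to 0.49, 222 genes). With 0.5 CPM added before the ratios, those of strands with few counts are drawn towards no change, and the opposite strand's median was 0.01. Low counts were argued against by a median of 0.33 against -0.02 in matched genic rows. Weaker termination with METTL3-3KR may explain it, as a hypothesis that was itself not tested. TKT shows the pattern with a downstream row at 1.62 and the gene at -0.99. AKR1B10 shows the reverse, with -3.16 past a gene at -0.99, and HEXIM2 does too, with -3.77 past a gene at -0.40. These genes were picked after their values were seen.

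Rows on chromosome 13 had a median log2 fold change of -0.24, with 49 of 567 higher and 116 lower, and rows on chromosome 8 of 0.10, with 250 of 1351 higher and 138 lower. Copy number was not tested.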
